A study of Homo sapiens and Mus musculus with 35 samples.

How the data were processed

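The series holds 35 samples from human and mouse erythroid cells, made to study the transcription factor LRF (gene ZBTB7A) as a repressor of fetal globin genes. RNA sequencing counts were used for 20 of them. The other 15 samples, 8 of accessible chromatin (ATAC-seq) and 7 of LRF binding or its input (ChIP-seq), are not analysed here. The human RNA libraries come from HUDEP-2, an established immortalised erythroid progenitor line, either wild type (WT) or labelled LRF knockout (KO). Cells were taken on day 0 in expansion medium (SFEM, described in the labels as early basophilic erythroblasts) and on day 5 in differentiation medium (EDM2, late basophilic erythroblasts), both with doxycycline, with 2 libraries in each of the 4 groups. The mouse RNA libraries come from spleen erythroblasts of C57BL/6 mice sorted without culture into Ter119+CD71+CD44highFSChigh cells (EB-L, basophilic) and Ter119+CD71+CD44midFSCmid cells (EB-S, polychromatophilic). They were WT or labelled LRF KO, with 3 libraries in each of the 4 groups.

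RNA was extracted with RNeasy columns and 125 ng went into total RNA libraries made with the NuGEN Encore Complete RNA-Seq DR Multiplex kit. The deposited tables hold counts per gene symbol, without scaling or filtering by the authors: the human table has 1 column per library and sequencing lane, with 2 lanes per library, and the mouse table has 1 column per library. The submitters' processing notes name Bowtie2, TopHat2, SAMtools, HTSeq and DESeq without versions or settings, with builds hg19 for human and mm9 for mouse. The gene annotation, the strand setting and the treatment of reads that align to several places are not stated, and the tables give no coordinates. Counts of near-identical genes are therefore uncertain: HBG1 and HBG2, HBA1 and HBA2, the mouse Hba-a copies, the mouse adult beta globin genes, histone genes and ribosomal protein genes with pseudogenes. The mouse adult beta globin gene Hbb-bs appears in the table under its older symbol Beta-s.

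The 2 lanes of each human library were summed after they were compared over genes with at least 20 counts, where chi-square per degree of freedom was 0.987 to 1.03. By a chi-square test over 11828 to 12791 genes the lanes differed slightly beyond sampling noise in WT day 0 number 1 (p = 0.0141), KO day 0 number 2 (p = 0.0169) and KO day 5 number 1 (p = 0.0317), and not in the other libraries (p of 0.1894 or more). Total counts ran from 22884555 to 34002602 in the 8 human libraries over 25372 listed genes, and from 972714 to 24975008 in the 12 mouse libraries over 23366 listed genes. Confidence intervals are 95% Wilson intervals for a share and 95% exact intervals for a ratio of counts, and a group without any count is given a floor of 3 counts per library. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

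Each species was fitted once with a mean for each of its 4 groups in edgeR 4.0.16 (R 4.3.3), using TMM scaling, filterByExpr with default settings, robust quasi-likelihood dispersions and the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene is called at an adjusted p under 0.05 without a limit on fold change. Tested genes numbered 15128 in human and 15938 in mouse. Levels are TMM-scaled counts per 1e6 counts (CPM) with standard deviations, unless the text says CPM of the library total, and log2 fold changes are given with ± their standard errors, derived from the estimate and its F statistic. The biological coefficient of variation was 48.5% in human and 85.4% in mouse. The labels do not say whether libraries came from separate cultures or animals, so p-values measure only the spread between libraries. The comparisons were KO against WT at each stage, the later against the earlier stage in WT, and the difference between the KO effects at both stages (the interaction).

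There were 20 gene lists: embryonic and fetal globins, adult globins, fetal globin regulators, heme synthesis and iron, red cell membrane and late erythroid genes, the BCL2 family and caspases, p53 targets, DNA replication, mitosis, glycolysis, the Notch pathway, interferon response, stem and early progenitor genes, ribosomal proteins, replication-dependent histones, and markers of megakaryocytes and platelets, granulocytes and monocytes, macrophages, B lymphocytes, and T and NK lymphocytes. The last 5 were included because a sort gate or a culture could hold such cells. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated from the data. The share of fetal HBG1 and HBG2, or of mouse embryonic Hbb-bh1 and Hbb-y, among all beta-like globin counts of a library was compared with a two-sided exact permutation test, for which 2 against 2 libraries allow no p below 0.333, 3 against 3 none below 0.1 and 3 against 2 none below 0.2. Overlaps of called genes were compared with the number expected by chance and tested with Fisher's exact test, one-sided.

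Genes named in the text follow a rule. It takes ZBTB7A, the members of both globin lists, BCL11A and KLF1 in each KO comparison. It adds the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out unnamed gene models and small RNAs, and up to 4 called members of each list with the smallest adjusted p. For the stage and interaction comparisons it takes the 5 largest in each direction, and for genes shared between species the 10 with the largest mean absolute log2 fold change. Any other gene is said to have been chosen after its values were seen. Groups, comparisons, lists, this rule and the alternative settings compared at the end, except those said to be added later, were written before the data were examined.

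Both mouse KO libraries numbered 1 stood apart from the others in depth and content. Every mouse count was therefore run again without them (10 libraries, 13498 genes tested, coefficient of variation 28.7%), an alternative chosen after seeing the data. Other alternatives were DESeq2 size factors in place of TMM, globin genes left out of the scaling, no filter on low counts, the DESeq2 1.42.0 Wald test, a fit of only the 2 groups compared, the human replicate number as a block, the number in the mouse column names as a block within each genotype for the comparisons between stages (added after the data were seen), a fold limit of 1 on the log2 scale for overlaps, other definitions of the globin share, and leaving out each library in turn. DESeq2 size factors moved the all-gene median log2 difference of the 12 mouse libraries from 0.50 to 0.97 for KO against WT in EB-L, from 0.55 to 0.98 in EB-S and from 0.07 to 0.22 between the WT stages. They moved it by less than 0.1 in the human libraries and in the 10 mouse libraries. A test on simulated data used 200 changed genes drawn from those with a mean of at least 5 CPM. It recovered 10% of 2-fold and 80% of 4-fold changes with the human design, where 11.9% of calls were unchanged genes. It recovered 0% and 4% with the 12 mouse libraries and 54% and 98% with the 10, where 2.4% and 4.3% of calls were unchanged genes. Recovery of genes below 5 CPM was not tested. Each gene had the same dispersion in every simulated library, unlike the real mouse set, where the KO libraries numbered 1 stood apart. Other tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.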

Results

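RNA sequencing counts were compared in human HUDEP-2 cells and in sorted mouse spleen erythroblasts, wild type (WT) or labelled as LRF knockout (KO). LRF is a zinc finger transcription factor encoded by ZBTB7A. The human set has 4 groups of 2 libraries, WT and KO at day 0 and at day 5, with total counts of 22884555 to 34002602. The mouse set has 4 groups of 3 libraries, WT and KO in the earlier EB-L and the later EB-S fraction, with total counts of 972714 to 24975008. Levels below are CPM as mean ± SD over the libraries of a group, and log2 fold changes carry their standard error.

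The gene named as the target was counted in every KO-labelled library. ZBTB7A stood at 209 and 192 CPM of the library total in WT day 0, at 282 and 200 in KO day 0, at 236 and 250 in WT day 5 and at 265 and 499 in KO day 5. Its fitted log2 difference was 0.27 ± 0.32 at day 0 (adjusted p = 1) and 0.67 ± 0.32 at day 5 (adjusted p = 0.827). Mouse Zbtb7a stood at 180, 162 and 173 CPM of the total in WT EB-L and at 62.7, 353 and 326 in KO EB-L numbers 1, 2 and 3. In EB-S it stood at 122, 83.4 and 174 in WT and at 51.2, 404 and 404 in KO. Without the KO libraries numbered 1, whose content is described further on, Zbtb7a was higher in KO by 0.91 ± 0.22 in EB-L (adjusted p = 0.00612) and by 1.94 ± 0.22 in EB-S (adjusted p = 5.23e-07). The EB-L call was lost when KO EB-L number 2 was left out (adjusted p = 0.159), and with all 12 libraries neither difference was called, with adjusted p = 0.92 and 0.746. Whole-gene counts do not show which exons were read and the labels do not state the deleted part, so counts of this gene cannot check the KO labels on which each direction below rests.

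The first question is whether KO-labelled erythroid cells made more fetal or embryonic globin RNA. In HUDEP-2 cells the share of the fetal gamma-globin genes HBG1 and HBG2 among all beta-like globin counts was 0.0466% ± 0.00281 in WT and 4.40% ± 2.54 in KO at day 0 (SD, n = 2 each). At day 5 it was 0.109% ± 0.0352 in WT and 10.1% ± 1.26 in KO. In mouse erythroblasts the share of the embryonic genes Hbb-bh1 and Hbb-y was 0.00389% ± 0.00313 in WT EB-L and 3.51% ± 0.324 in KO EB-L (SD, n = 3 each). In EB-S it was 0.00339% ± 0.000879 in WT and 4.73% ± 0.402 in KO. Of these mouse genes only Hbb-bh1 was called higher (10 libraries, values given below), so the rise cannot be read as one of Hbb-y.

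Every KO library lay above every WT library of its stage in these shares. The highest WT and lowest KO shares were 0.0486% (95% Wilson interval 0.0439% to 0.0538%) and 2.60% (2.57% to 2.64%) at day 0, and 0.134% and 9.18% (9.14% to 9.23%) at day 5. In EB-L they were 0.00735% (0.00589% to 0.00917%) and 3.20% (3.16% to 3.24%), and in EB-S 0.00401% (0.00304% to 0.00529%) and 4.39% (3.87% to 4.98%). The exact permutation p was 0.333 at each human stage and 0.1 at each mouse stage, the smallest that these group sizes allow. The day 0 difference of 4.35 points rests on libraries that differ widely and ranged from 2.56 to 6.15 points when 1 library was left out. In mouse, Hbb-b1, Hbb-b2 and the Hba-a copies were at or near 0 counts and Beta-s carried nearly all adult beta counts. Hba-a2 had 28 counts over the WT EB-L libraries (0.363 CPM), so counts of these near-identical genes cannot be read as adult alpha globin RNA. Whether adult beta globin was undercounted was not tested, and if it was, the mouse shares lie too high.

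**Figure D1:**
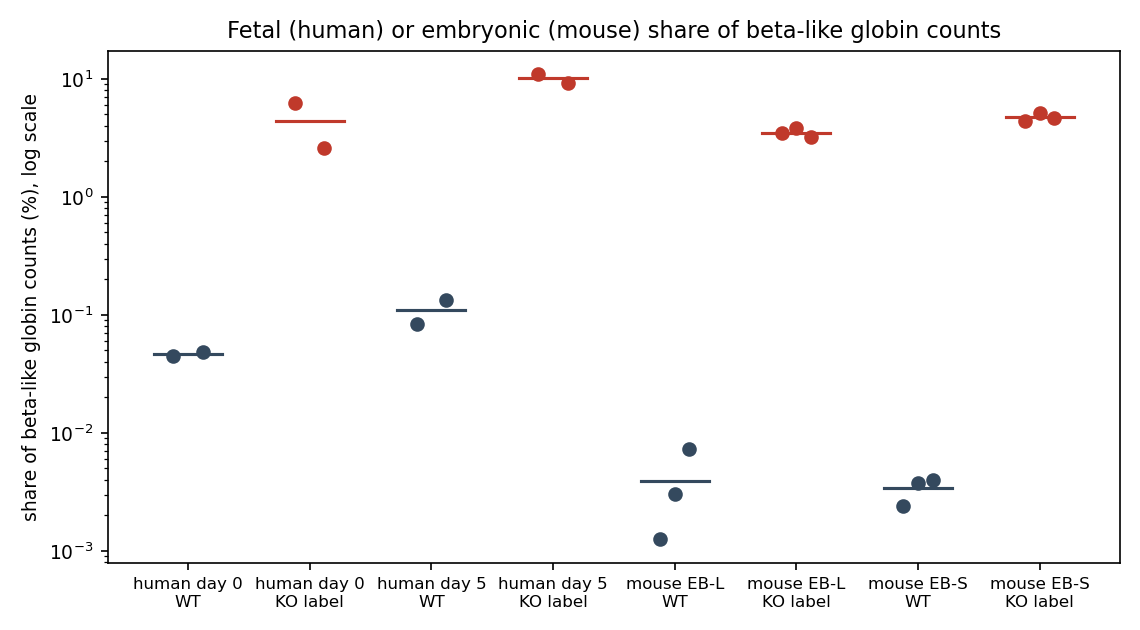
Share of HBG1 and HBG2 (human) or Hbb-bh1 and Hbb-y (mouse) among beta-like globin counts, in percent on a log axis, with 1 point per library and a bar at each group mean. The highest WT library lies at 0.134% in human and 0.00735% in mouse, and the lowest KO-labelled library at 2.60% and 3.20%. In mouse, Hbb-bh1 but not Hbb-y was called higher in the fit of 10 libraries.

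KO against WT at day 0 asks which genes differ in undifferentiated HUDEP-2 cells. The fetal globin genes HBG1 and HBG2 rose by 5.69 ± 0.64 and 5.66 ± 0.68 on the log2 scale, from 3.99 ± 0.537 to 206 ± 84.1 CPM and from 11.3 ± 6.03 to 570 ± 229 CPM (n = 2 each). The tyrosine phosphatase gene PTPN13, without counts in WT, reached 42.8 ± 9.12 CPM in KO, at least 489-fold higher (floor of 3 counts per library). RUNX3, which encodes a transcription factor of lymphoid and other lineages, fell by 5.43 ± 0.64 on the log2 scale, from 16.9 to 0.389 CPM. Adult HBB was at 33020 ± 16000 CPM in WT and 17820 ± 3960 in KO (log2 -0.89 ± 0.49, adjusted p = 0.969).

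In all, 16 genes were called at day 0, with 10 higher and 6 lower, and 874 genes had an unadjusted p under 0.05. Among the called genes, adjusted p was 0.000781 for PTPN13, 0.0280 for HBG1, 0.0370 for HBG2 and 0.0193 for RUNX3. Other rises were those of the receptor phosphatase gene PTPRS (5.43 ± 0.79), the tubulin gene TUBB4A (4.96 ± 0.52), the nutrient-sensing GTPase gene RRAGD (3.77 ± 0.51), the aldose reductase gene AKR1B1 (3.73 ± 0.51) and the zinc finger gene PLAGL1 (1.92 ± 0.24). Other falls were those of the glycosyltransferase gene GALNT14 (-4.46 ± 0.62), the lysine breakdown gene AASS (-4.21 ± 0.54), SLFN13 (-3.32 ± 0.47) and the mitochondrial topoisomerase gene TOP1MT (-1.78 ± 0.23). The embryonic genes HBZ and HBE1 were at log2 3.32 ± 0.74 (adjusted p = 0.251) and 1.70 ± 1.02 (adjusted p = 0.969). BCL11A and KLF1, which encode known regulators of globin switching, were at log2 0.13 ± 0.39 and -0.11 ± 0.24, each with adjusted p = 1, and HBD, HBA1 and HBA2 at -0.29, 0.35 and -0.32 were not called either.

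With a fit of only both groups compared, 143 genes were called at day 0, and with the replicate block 59. The count was 3 without KO day 0 replicate 1 and 9 without WT day 0 replicate 2, and of 14 named calls those of PTPN13 and TUBB4A were kept in each fit with 1 library left out. HBG1 lost its call without WT replicate 1 (adjusted p = 0.345), WT replicate 2 (0.312) or KO replicate 1 (0.0927), and HBG2 without any 1 of the 4 libraries, with adjusted p from 0.0978 to 0.289.

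Among the lists at day 0, the embryonic and fetal globins were higher in KO, with 2 of 4 members called over all genes and 3 adjusted over the list alone. Their median log2 difference was 4.49 and the camera adjusted p 2.74e-20, which became an adjusted p = 0.077 with an estimated correlation. Macrophage markers were higher without a called member of 5, while 2 passed when adjusted over the list alone (adjusted p = 0.00998; adjusted p = 0.317 with an estimated correlation). The interferon response list (24 tested, median -0.48, or -0.41 with members at 0 counts set to their bound) and replication-dependent histones (58 tested, median -0.30) were lower without a called member. Their adjusted p were 0.0187 and 8.62e-06, and adjusted p = 0.511 and 0.661 with an estimated correlation. The other lists were not called, with mitosis at adjusted p = 0.0680, megakaryocyte markers at 0.201, BCL2 family and ribosomal proteins at 0.224, the Notch pathway at 0.239, glycolysis at 0.326, and p53 targets and T and NK markers at 0.381. Red cell membrane genes stood at 0.450, fetal globin regulators and stem genes at 0.475, heme genes at 0.497, DNA replication at 0.517, adult globins at 0.636, granulocyte markers at 0.823 and B cell markers at 0.841.

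At day 5 the same question was asked of differentiating HUDEP-2 cells. HBG1 rose from 13.9 ± 9.28 to 1102 ± 548 CPM and HBG2 from 57.1 ± 32.2 to 3646 ± 1910 CPM (n = 2 each), by 6.31 ± 0.65 and 6.00 ± 0.69 on the log2 scale. PTPN13 again rose, by 6.95 ± 0.56, as did HIF3A, a hypoxia-inducible factor subunit gene, by 7.30 ± 0.98. The muscle filament gene DES, the eosinophil peroxidase gene EPX and TRO had no counts in WT and were at least 173-fold, 130-fold and 100-fold higher in KO. GALNT14, without counts in KO, was at least 43.4-fold lower, and RUNX3 fell by 3.97 ± 0.61.

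In all, 30 genes were called at day 5, with 21 higher and 9 lower, and 926 had an unadjusted p under 0.05. Adjusted p was 0.0123 for HBG1, 0.0199 for HBG2, 0.00257 for PTPN13, 0.0420 for HIF3A, 0.00715 for DES, 0.0184 for EPX, 0.00982 for TRO, 0.00800 for GALNT14 and 0.0313 for RUNX3. HSPA12B, with 3 counts in WT, was 169 times higher in KO (counting interval 57.4 to 823; adjusted p = 0.00257). Other falls were those of the formin gene FMNL3 (-4.08 ± 0.56), the talin gene TLN2 (-3.96 ± 0.59), the interferon-induced gene XAF1 (-3.06 ± 0.50), the cation channel gene PKD2 (-2.58 ± 0.42) and FGFRL1 (-1.78 ± 0.29). HBZ was at 44.6 ± 32.4 CPM in WT and 1290 ± 689 in KO (log2 4.85 ± 0.79, adjusted p = 0.0818), and HBE1 at log2 1.77 ± 0.99 (adjusted p = 0.907). HBB, HBD, HBA1, HBA2, BCL11A and KLF1 were at log2 -0.49, -0.08, 0.41, 0.32, 0.16 and 0.14, each with adjusted p = 1.

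The count was 0 in a fit of only both groups compared and 70 with the replicate block. It was 291 without KO day 5 replicate 1, 155 without KO replicate 2 and 19 without WT replicate 1, which detected 18070 genes against 13642 to 15871 in the other human libraries. HBG1 lost its call without KO replicate 1 (adjusted p = 0.0526) or KO replicate 2 (0.0835), and HBG2 without any 1 of the 4 libraries, with adjusted p from 0.106 to 0.199. Of 16 named calls 7 were kept in each such fit, and without WT replicate 1 or 2 HIF3A was at adjusted p = 0.421 and 0.753 and PKD2 at 0.065 and 0.119. EPX (0.065), RUNX3 (0.0814) and XAF1 (0.0814) lost their calls without WT replicate 1, and TLN2 (0.0675) and FGFRL1 (0.0597) without WT replicate 2.

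Among the lists at day 5, the embryonic and fetal globins were higher in KO, with 2 of 4 members called and 3 adjusted over the list alone, a median of 5.43 and an adjusted p = 5.06e-24 (adjusted p = 0.0545 with an estimated correlation). Macrophage markers were higher without a called member of 5, with 3 adjusted over the list alone (adjusted p = 4.98e-05; adjusted p = 0.0961 with an estimated correlation). Mitosis genes (30 tested, median 0.34) and replication-dependent histones (58 tested, median 0.26) were higher as sets, also without a called member. Their adjusted p were 0.000123 and 0.00781, and adjusted p = 0.876 for both with an estimated correlation. The other lists had adjusted p from 0.0693 for ribosomal proteins to 0.893 for adult globins and T and NK markers. XAF1 was the called member of the interferon list, which had an adjusted p = 0.454.

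WT day 5 against WT day 0 describes the differentiation of the unmodified line. Red cell membrane and late erythroid genes were higher at day 5 as a set (35 tested, median 0.48, adjusted p = 2.74e-06), as were heme synthesis and iron genes (25 tested, 0.36, adjusted p = 0.00304), adult globins (4 tested, 1.24, adjusted p = 0.00304) and embryonic and fetal globins (4 tested, 2.10, adjusted p = 2.74e-06). None of their members was called over all genes, and 3 embryonic and fetal globins passed when adjusted over the list alone. Adjusted p with an estimated correlation was 0.693, 0.693, 0.676 and 0.475 for these lists. B cell markers were higher (median 1.80, or 1.47 with members at 0 counts set to their bound; adjusted p = 0.0135), and glycolysis (-0.29, adjusted p = 0.0294) and histones (-0.27, adjusted p = 0.000244) were lower, with 0.475, 0.693 and 0.693 as adjusted p with an estimated correlation.

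Single genes called between the WT stages were 4, all lower at day 5, and 796 had an unadjusted p under 0.05. The aminopeptidase gene ANPEP fell from 35.4 ± 3.88 to 2.15 ± 0.908 CPM (log2 -4.04 ± 0.41, adjusted p = 0.00932), the glutathione transferase gene GSTM3 by 2.87 ± 0.33 (adjusted p = 0.0208) and EPAS1, a hypoxia-inducible factor gene, by 2.58 ± 0.25 (adjusted p = 0.00932). HSPA12B, chosen after its values were seen, fell by 5.30 ± 0.64 (adjusted p = 0.0213). The count was 2 without WT day 0 replicate 1, and GSTM3 was then at adjusted p = 0.116 and without WT day 5 replicate 1 at 0.0779.

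Whether the KO effect differed between day 0 and day 5 was tested directly, and edgeR called 0 genes, with 271 at an unadjusted p under 0.05 and 1 call by DESeq2. As sets, mitosis genes (median 0.58, adjusted p = 3.75e-09) and histones (0.55, adjusted p = 5.09e-13) had a more positive KO effect at day 5, with adjusted p = 0.754 for both with an estimated correlation. No histone was called over all genes and 2 passed when adjusted over the list alone. The interaction count was 7 without KO day 5 replicate 1 and 3 without KO day 5 replicate 2. The called genes of the human stages overlapped, with 6 genes higher at both (10 and 21 called, 0.0139 expected by chance, Fisher's exact p = 6.83e-16) and 4 lower at both (6 and 9 called, 0.00357 expected, Fisher's exact p = 8.66e-13). Genes are not independent units and both stages share 1 fit, so these p-values do not measure the spread between libraries. The labels do not say whether the same cultures or clones were used at both stages. If they were, differences between them would recur at both, and the overlap would not be a replication. The shared rises were HBG1, HBG2, PLAGL1, PTPN13, RRAGD and TUBB4A and the shared falls included GALNT14, RUNX3 and TOP1MT.

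In the mouse, the KO libraries numbered 1 differed from the other 10 in depth and content. Their totals were 972714 in EB-L and 1035361 in EB-S, and they detected 22595 and 22640 genes against 16584 to 20072 in the others. Olfactory and vomeronasal receptor genes took 3.09% and 3.58% of their counts against 0.018% to 0.059%, and the ribosomal RNA precursor Rn45s took 1.25% and 0.81% against 16.1% to 20.8%. Their median rank correlation with the other libraries was 0.663 and 0.606 across genes, against 0.840 to 0.866 for the others. Gene values, list values and list counts below come from the fit without them (10 libraries, added after seeing the data), unless 12 are named. The number of genes called in a comparison is given with all 12 libraries first.

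**Figure D2:**
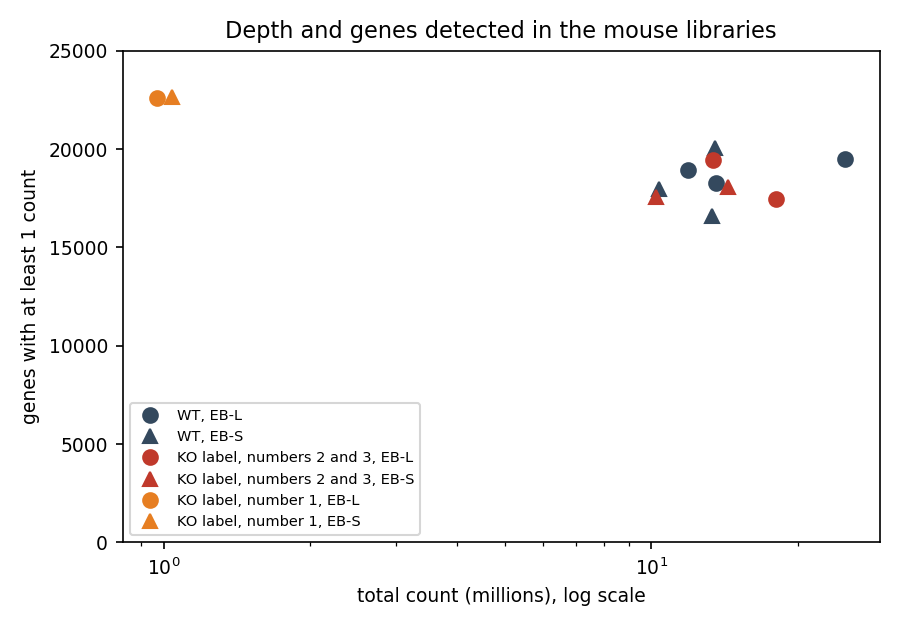
Genes with at least 1 count against the total count (log axis) for the 12 mouse libraries, coloured by label and number, with circles for EB-L and triangles for EB-S. The KO libraries numbered 1 lie at 972714 and 1035361 counts and 22595 and 22640 genes.

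KO against WT in EB-L asks which genes differ in basophilic spleen erythroblasts. The embryonic globin genes Hba-x and Hbb-bh1 rose from 15.8 ± 19.0 to 25230 ± 5330 CPM and from 2.34 ± 2.47 to 1525 ± 514 CPM (n = 3 and 2), with log2 fold changes of 10.67 ± 1.88 and 9.45 ± 0.84. Klf1, which encodes an erythroid activator of adult globin, fell by 1.05 ± 0.23, and Bcl11a rose by 1.09 ± 0.23, and neither was called with all 12 libraries. The Notch ligand gene Dll4 rose by 7.84 ± 0.40 and the glycolytic regulator gene Pfkfb4 by 7.12 ± 0.51. The extracellular matrix gene Reln fell by 4.42 ± 0.28 and the interferon-induced gene Oas3 by 3.64 ± 0.32.

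With all 12 libraries, 72 genes were called in EB-L (49 higher, 23 lower; 1524 at an unadjusted p under 0.05), and with 10 libraries 1751 (891 higher, 860 lower; 3181). All 72 were among the 1751. In the 10-library fit, adjusted p was 0.0126 for Hba-x, 9.29e-05 for Hbb-bh1, 0.00242 for Klf1, 0.00204 for Bcl11a, 1.19e-11 for Dll4, 1.83e-06 for Pfkfb4, 6.70e-11 for Reln and 3.77e-08 for Oas3. Prlh, a peptide hormone gene without counts in WT, was at least 125-fold higher, and Fam25c, with 1 count in WT, was 796 times higher (counting interval 142 to 31500). Further large rises were those of the ubiquitin ligase gene Fbxo2 (8.86), the matrix gene Bgn (8.44) and Foxh1 (7.39). Further falls were those of the lymphocyte receptor gene Tnfrsf13c (-6.58), Slfn9 (-5.45), Zfp948 (-5.23), Ppip5k1 (-4.56), Cpne2 (-4.48), the redox gene Srxn1 (-4.47) and Ttc39a (-4.43). Beta-s was at log2 -0.63 ± 0.34 (adjusted p = 0.285) and Hbb-y at 0.39 ± 1.08 (adjusted p = 0.900). Hba-a2, with 28 counts in WT and none in KO, was called lower (at least 2.36-fold, adjusted p = 0.0312). With so few counts of a near-identical gene, this call cannot be read as a fall of adult alpha globin RNA.

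The 12-library count was 264 without KO number 1, 45 and 40 without the WT libraries whose columns are numbered 1 and 3, and Hba-x and Hbb-bh1 had adjusted p = 0.167 and 0.115 with all 12. The 10-library count was 825 without KO number 2 and 887 without KO number 3, where Hba-x was at adjusted p = 0.0621 and 0.0540 (0.0589 without WT column 3), Bcl11a at 0.0782 without number 2 and Klf1 at 0.166 without number 3. Tnfrsf13c was at 0.125 and 0.165 without KO numbers 2 and 3, and Hba-a2 at 0.222 and 0.170 and, without WT column 1, at 0.166.

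Among the lists in EB-L (10 libraries), glycolysis genes were higher, with 9 of 21 called higher and 1 lower, such as the aldolase gene Aldoa (3.20) and the lactate transporter gene Slc16a3 (3.93), while Pfkm fell (-1.49; list adjusted p = 0.000164, and adjusted p = 0.177 with an estimated correlation). DNA replication genes had 8 of 33 called lower and 14 adjusted over the list alone, such as Rfc4 (-0.90), Cdt1 (-0.82) and Ccne1 (-0.80), with a list adjusted p = 0.000271 (adjusted p = 0.606 with an estimated correlation). Red cell membrane and late erythroid genes had 7 called lower, such as Icam4 (-1.13) and the water channel gene Aqp1 (-1.01), and 2 higher of 32, the red cell pyruvate kinase gene Pklr (1.83) among them (list adjusted p = 0.0377; adjusted p = 0.671 with an estimated correlation). Ribosomal protein genes had 11 of 79 called lower, such as Rpl41 (-0.95) and Rps2 (-0.86), and histones 3 of 59 lower, such as Hist3h2ba (-1.24). Their list adjusted p were 0.000164 and 0.00905, and adjusted p = 0.634 and 0.702 with an estimated correlation. Rfc4, Cdt1, Ccne1, Aqp1 and Rps2 each lost their call without KO EB-L number 2 or number 3, with adjusted p from 0.0696 to 0.249, and Icam4, Rpl41 and Hist3h2ba without number 3, with adjusted p of 0.139, 0.257 and 0.126. The 12-library fit called 1 glycolysis gene and no member of the other lists of this paragraph in EB-L.

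Markers of other blood cells were higher beside these groups in EB-L. Granulocyte markers had 6 of 14 called higher (9 adjusted over the list alone), such as S100a9 (4.97) and S100a8 (5.99), macrophage markers 6 of 15 (9), such as Vcam1 (3.25), and B cell markers 4 of 11 (7), such as Cd74 (5.56). Adjusted p was 1.02e-07, 6.94e-05 and 4.39e-05, and adjusted p = 0.0952, 0.0912 and 0.0976 with an estimated correlation. The embryonic globin list (2 of 3 called, median 9.45) had an adjusted p = 0.00217 and the Notch list (3 of 21 higher, 1 lower) 0.0420, with adjusted p = 0.0964 and 0.444 with an estimated correlation. Lists that were not called were fetal globin regulators (5 higher and 2 lower of 39, adjusted p = 0.258), with Chd3 (2.48) and Ldb1 (1.71) higher, heme and iron genes (2 and 2 of 24, 0.734), with Hmox1 (4.07) higher and Steap3 (-1.90) lower, and interferon response (1 and 4 of 26, 0.188), with Ddx58 (2.82) higher. Mitosis (1 of 30 lower, Ube2c at -1.47, 0.542), p53 targets (Sesn2 at 1.62, 0.363), the BCL2 family (1 higher, 2 lower, 0.597), stem genes (2 and 2 of 13, 0.978), megakaryocyte markers (2 higher and 1 lower of 11, 0.109), T and NK markers (0.188) and adult globins (0.188) were not called either. With all 12 libraries at the preset correlation, mitosis (camera adjusted p = 1.7e-06), heme and iron genes (0.000268), fetal globin regulators (0.0247) and adult globins (0.0316) were called lower. In that fit T and NK (0.000276) and megakaryocyte markers (0.00838) were called higher, and none of these calls held with an estimated correlation. The adult globin list call rests on 2 tested genes, neither called over all genes, with Hba-a2 at 0 counts in KO. The median of that list was -3.38, or -1.10 with Hba-a2 set to its bound.

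KO against WT in EB-S asks the same of polychromatophilic erythroblasts. Hba-x rose from 17.7 ± 13.8 to 77940 ± 9880 CPM and Hbb-bh1 from 4.85 ± 1.71 to 8109 ± 1060 CPM (n = 3 and 2). Mitosis genes fell in KO, with 29 of 30 called lower, and replication-dependent histones with 47 of 59 called lower (adjusted p = 0.132 for each list with an estimated correlation). No member of either list was called with all 12 libraries. Klf1 fell by 1.57 ± 0.24 and Bcl11a rose by 1.47 ± 0.25, and neither was called with all 12 libraries. The invariant chain gene Cd74, a B cell and antigen presentation marker, rose from 3 counts over the WT libraries to 73.5 ± 2.94 CPM.

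With all 12 libraries, 95 genes were called in EB-S (61 higher, 34 lower; 1521 at an unadjusted p under 0.05), and with 10 libraries 3583 (1891 higher, 1692 lower; 4712), among which were all 95. In the 10-library fit, Hba-x was at log2 12.09 ± 1.97 (adjusted p = 0.00452), Hbb-bh1 at 10.70 ± 0.87 (adjusted p = 2.35e-05), Klf1 at adjusted p = 1.88e-05 and Bcl11a at adjusted p = 7.51e-05. Prlh, with 2 counts in WT, was 964 times higher (counting interval 266 to 7970), Cd74, with 3 counts, 793 times (271 to 3850), S100a9, with 1 count, 472 times (84.0 to 18700), and the granulocyte gene Ngp, without counts in WT, at least 28.6-fold. Ndrg2 (8.87 ± 0.30) and Pfkfb4 (8.26 ± 0.54) rose, and Slfn9 (-5.46), Tnfrsf13c (-4.71), Srxn1 (-4.53), Lrp8 (-4.43), the tachykinin gene Tac2 (-4.33), Pbx3 (-4.28), Plek2 (-4.24) and Klhl21 (-4.18) fell. Beta-s was at log2 -0.28 ± 0.34 (adjusted p = 0.642), Hbb-y at 0.66 ± 0.97 (adjusted p = 0.708) and Hba-a2 at 0.38 ± 0.95 (adjusted p = 0.842).

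The 12-library count in EB-S was 404 without KO number 1, 47 and 48 without KO numbers 2 and 3, and 49 and 59 without the WT libraries whose columns are numbered 1 and 4, and Hba-x and Hbb-bh1 had adjusted p = 0.0852 and 0.0602 with all 12. The 10-library count was 2341 and 2353 without KO numbers 2 and 3, and Tnfrsf13c was not called without KO number 2 or 3 or WT column 4.

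Among the lists in EB-S (10 libraries), the mitosis list had a median of -1.59, with Ube2c at -3.01, Cdk1 at -2.37, Plk1 at -2.35 and Ccnb1 at -2.31, and an adjusted p = 5.73e-23 (adjusted p = 0.132 with an estimated correlation). Histones had a median of -1.94, with Hist1h2an at -2.68 and Hist1h2ab at -2.46, and an adjusted p = 5.67e-25 (adjusted p = 0.132 with an estimated correlation). DNA replication genes had 20 of 33 called lower, such as Rrm2 (-1.50) and Ccne1 (-1.49), and 1 higher, with a median of -0.81 and an adjusted p = 7.07e-06 (adjusted p = 0.441 with an estimated correlation). Glycolysis genes had 11 of 21 called higher, such as Aldoa (4.02) and Ldha (2.01), with a median of 1.09 and an adjusted p = 0.000397 (adjusted p = 0.132 with an estimated correlation). The 12-library fit called 0 DNA replication genes and 1 glycolysis gene in EB-S. The p53 targets had 4 of 18 called higher, such as Sesn2 (3.52) and Ccng1 (2.34), and 1 lower, with an adjusted p = 0.00999 (adjusted p = 0.132 with an estimated correlation). With all 12 libraries no p53 target was called and the list was not called either (camera adjusted p = 0.217).

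Markers of other blood cells were higher in KO EB-S beside these groups, and these calls held with an estimated correlation. Granulocyte markers had 12 of 14 called higher, such as S100a8 (6.43) and Lcn2 (5.76), with a median of 4.89, or 3.97 with members at 0 counts set to their bound, and an adjusted p = 1.38e-10 (adjusted p = 0.0163 with an estimated correlation). B cell markers had 7 of 11 called higher (8 adjusted over the list alone), such as Cd79a (4.84) and Cd22 (4.02), with an adjusted p = 2.66e-09 (adjusted p = 0.0163 with an estimated correlation). Macrophage markers had 9 of 15 called higher (10 adjusted over the list alone), such as Vcam1 (3.58) and Axl (2.20), with an adjusted p = 0.000453 (adjusted p = 0.0457 with an estimated correlation). In the 12-library fit, 5 of 18 granulocyte, 2 of 13 B cell and 1 of 15 macrophage markers were called higher in EB-S, and in EB-L 0, 0 and 1. In that fit, the granulocyte, B cell, macrophage and glycolysis list calls in EB-S held with an estimated correlation at adjusted p = 0.0178, 0.0267, 0.0267 and 0.0267, and the granulocyte and macrophage calls in EB-L at adjusted p = 0.0263 each. The EB-L list calls did not hold with 10 libraries. With 12 and 10 libraries the EB-L medians were 2.64 and 2.66 for granulocyte and 2.71 and 2.24 for macrophage markers. They were 1.79 and 0.16 for the Notch list and 1.67 and -0.02 for the stem list. A rise in the 12-library fit is therefore not particular to blood cell markers, and these values add no separate support.

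Embryonic globins in EB-S (2 of 3 called, adjusted p = 0.00839; adjusted p = 0.132 with an estimated correlation) and ribosomal proteins (13 of 79 lower, 2 higher, adjusted p = 0.0445; adjusted p = 0.776 with an estimated correlation) were called as lists. Other lists were not called. Fetal globin regulators had 10 of 39 higher and 7 lower (adjusted p = 0.470), with the chromatin genes Chd3 (2.60), Kdm1a (1.92) and Gatad2b (1.81) and the erythroid cofactor gene Ldb1 (2.01) higher. Heme and iron genes had 7 of 24 higher, such as Hmox1 (4.00) and Tfr2 (1.61), and 2 lower, such as the iron reductase gene Steap3 (-2.63; adjusted p of the list = 0.262). Red cell membrane genes had 6 of 32 higher, such as Pklr (4.03) and Xk (1.36), and 7 lower, such as Icam4 (-2.64) and Aqp1 (-1.52; adjusted p of the list = 0.897). The remaining lists were the Notch pathway (4 and 2 of 21, 0.295; Dll4 at 7.08), interferon response (3 and 3 of 26, 0.897; Ddx58 at 4.31), the BCL2 family (4 and 1 of 24, 0.566; Bcl2l11 at 1.66), stem genes (2 and 1 of 13, 0.895; Runx1 at 1.92), megakaryocyte markers (2 and 2 of 11, 0.166; Tubb1 at 7.02), T and NK markers (2 of 9 higher, 0.205; Tcf7 at 4.28) and adult globins (0 of 2, 0.897). With all 12 libraries at the preset correlation, red cell membrane genes (median -0.65, camera adjusted p = 5.52e-06) and heme and iron genes (0.00859) were called lower. In that fit T and NK markers (0.000139) and the Notch pathway (0.0211) were called higher, and none of these calls held with an estimated correlation.

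**Figure D3:**
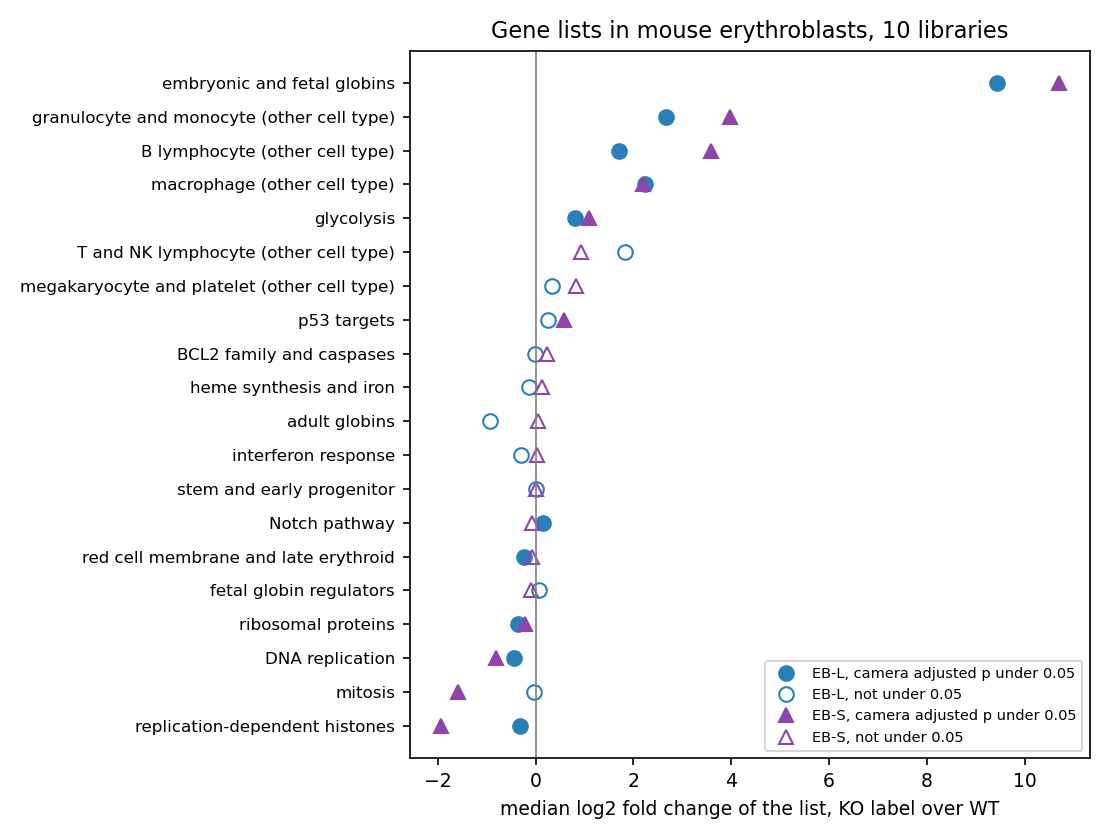
Median log2 fold change (KO label over WT, 10 libraries) of the 20 gene lists in EB-L (circles) and EB-S (triangles), with members at 0 counts in a group set to their bound and filled symbols for a camera adjusted p under 0.05 at the preset correlation. Histones and mitosis lie at -1.94 and -1.59 in EB-S and at -0.32 and -0.03 in EB-L.

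WT EB-S against WT EB-L describes maturation in unmodified spleen erythroblasts. Ribosomal protein genes were lower in EB-S, with 68 of 79 called (0 with all 12 libraries), such as Rps20 (-1.37 ± 0.19) and Rpl32 (-1.38 ± 0.20), while the list had an adjusted p = 0.384 with an estimated correlation. Of 32 red cell membrane and late erythroid genes 14 were called higher, such as the ubiquitin ligase genes Trim58 (2.82 ± 0.27) and Trim10 (1.89 ± 0.25), and 2 lower (adjusted p of the list = 0.402 with an estimated correlation). Beta-s rose from 63870 ± 7230 to 190600 ± 72000 CPM (n = 3 each; log2 1.58 ± 0.31, adjusted p = 0.000887), and 11 of 26 interferon-response genes were called higher, such as Isg15 (1.82) and Rsad2 (2.73; adjusted p of the list = 0.402 with an estimated correlation). Bcl11a fell by 1.35 ± 0.22 (adjusted p = 0.000187).

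Between the WT stages edgeR called 0 genes with all 12 libraries, with 756 at an unadjusted p under 0.05 and 45 called by DESeq2, and with 10 libraries 2530 (1037 higher, 1493 lower; 4292). The excess of lower calls depended on the scaling and the test, with 1164 higher and 1195 lower by DESeq2 size factors and 1405 and 1288 by DESeq2. The largest called rises were those of the transcriptional regulator gene Arid5b (4.83), the nuclear transport gene Xpo7 (4.74), Tcp11l2 (4.61), Oas1e (4.31) and Tmem140 (4.08), and the largest falls those of Tagln2 (-2.96), Bcat2 (-2.75), the mitochondrial chaperonin gene Hspe1 (-2.74), Ppp1r14b (-2.68) and C1qbp (-2.59). With the 12 libraries, 1916 were called in a fit of only both WT groups and 1955 with the column number as a block within each genotype. The 12-library count was otherwise 5 and 4 without the WT EB-S libraries whose columns are numbered 3 and 4, and the 10-library count was 1609 without WT EB-L column 1 or 3 and 1647 without WT EB-S column 3.

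List values between the WT stages (10 libraries) were medians of -0.88 for ribosomal proteins (adjusted p = 1.48e-30), 0.53 for red cell genes (8.62e-08), 1.02 for interferon response (4.62e-06), -0.50 for mitosis (12 of 30 lower, such as Ccnb1 at -1.06; 4.36e-06) and 0.38 for heme and iron genes (8 higher and 3 lower of 24; 0.0359). DNA replication (10 of 33 lower, such as Mcm3 at -1.05, and 1 higher) had an adjusted p = 0.000747, macrophage markers (4 of 15 higher, such as Lgmn at 3.20) 0.0245 and adult globins (1 of 2 higher) 0.0359. Glycolysis had a positive median of 0.16 but 7 of 21 members called lower, such as Ldha (-2.11) and Gpi1 (-1.90), and the test read the list as lower (adjusted p = 0.0359). None of these calls held with an estimated correlation, with adjusted p from 0.384 to 0.531. Fetal globin regulators (2 higher and 9 lower of 39, such as Nfia at -1.94) were at adjusted p = 0.0524, megakaryocyte markers at 0.0637, T and NK markers at 0.118, histones at 0.269, the BCL2 family and embryonic globins at 0.299, B cell markers at 0.307, the Notch pathway at 0.329, stem genes at 0.438, p53 targets at 0.633 and granulocyte markers at 0.679. With all 12 libraries at the preset correlation, heme and iron genes (camera adjusted p = 0.778), adult globins (0.191) and glycolysis (0.0596) lost their list calls. The other list calls of this paragraph were kept, and megakaryocyte markers were called higher (0.00914).

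The difference between the KO effects in EB-S and EB-L was tested directly. Mitosis genes had a more negative KO effect in EB-S, with 27 of 30 called (29 adjusted over the list alone, 0 called with all 12 libraries) and a median of -1.58, and so did histones, with 24 of 59 called (42 adjusted over the list alone, 0 with all 12) and a median of -1.55. Adjusted p was 2.09e-45 for mitosis and 5.16e-37 for histones, and adjusted p = 0.134 for both with an estimated correlation. Examples are Ccnb1 (-2.08 ± 0.31), Cdk1 (-2.12 ± 0.36), the kinetochore gene Spc25 (-2.43 ± 0.36) and Hist1h1d (-2.10 ± 0.38). More positive in EB-S were the KO effects on Cd74 (3.94 ± 0.81), the iron-regulatory gene Aco1 (2.75 ± 0.51), Ccng1 (2.25 ± 0.31) and Pklr (2.20 ± 0.39).

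For this difference edgeR and DESeq2 each called 0 genes with all 12 libraries, with 98 at an unadjusted p under 0.05 in edgeR, and with 10 libraries edgeR called 397 (165 higher, 232 lower; 1928) and DESeq2 655. With the column number as a block within each genotype, a setting added after the data were seen, edgeR called 19 and 873 (457 higher, 416 lower). The 10-library count was 123 and 177 without KO EB-L numbers 2 and 3, 125 and 108 without KO EB-S numbers 2 and 3, 254 and 249 without WT EB-L columns 1 and 3, and 647 without WT EB-S column 3, and of 30 named calls 14 were kept in each of these fits, among them Ccnb1, Cdk1, Spc25, Hist1h1d, Cd74, Aco1, Ccng1 and Pklr. Other called lists were B cell markers (median 1.51, adjusted p = 0.00200), granulocyte markers (0.00475), p53 targets (0.00904), DNA replication (median -0.37, adjusted p = 0.0297, though its 2 called members E2f2 and Mcm6 were at 1.29) and red cell genes (0.0408). Their adjusted p with an estimated correlation ran from 0.134 to 0.774. With all 12 libraries at the preset correlation, B cell (camera adjusted p = 0.00543) and granulocyte markers (0.000662) kept their list calls. The p53 targets (0.144), DNA replication (0.528) and red cell genes (0.635) lost theirs.

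**Figure D4:**
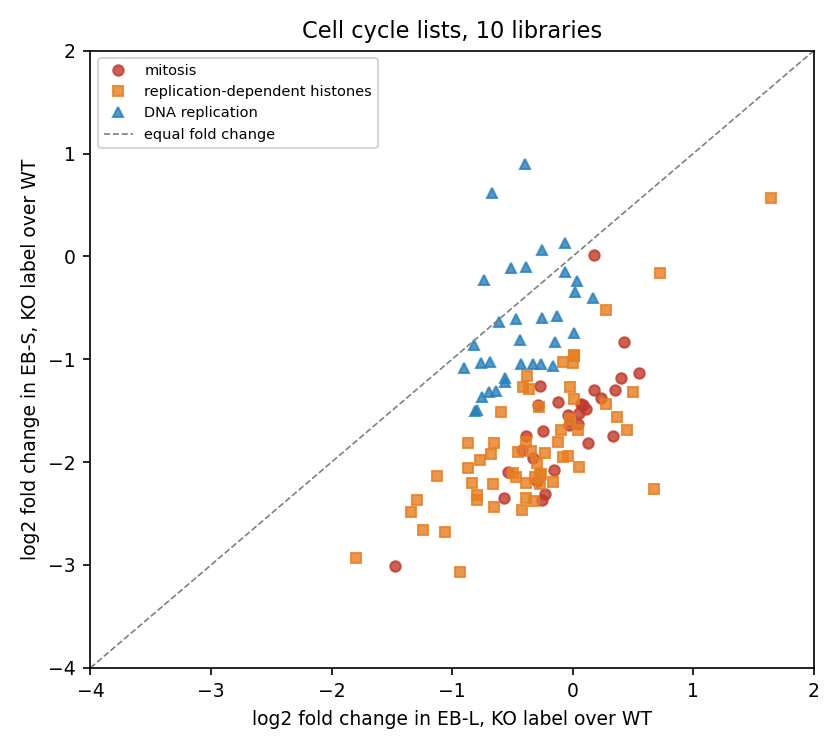
Log2 fold change (KO label over WT, 10 libraries) in EB-S against EB-L for the members of the mitosis, histone and DNA replication lists, with 1 point per gene and a dashed line at equal change. Below the line lie 30 of 30 mitosis genes and 59 of 59 histones.

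Genes called in both mouse stages were compared with the number expected if genes and stages were independent. Neither holds, so the expected numbers and p-values do not measure the spread between libraries. Values of the same column number correlated between stages at 0.44, 0.11 and 0.34 in WT and 0.12 in KO with 10 libraries. With all 12, the KO values were 0.89, 0.85 and 0.85, where number 2 reached 0.86 with another number. These 12-library values are deviations from a group mean that KO number 1, standing apart at both stages, dominates, so they show no pairing by number. With all 12 libraries, 25 were higher in both (49 and 61 called, 0.188 expected, Fisher's exact p = 7.25e-50) and 13 lower in both (23 and 34 called, 0.0491 expected, Fisher's exact p = 1.53e-30). With 10 libraries, 704 were higher in both against 125 expected and 620 lower in both against 108 expected, while 7 changed in opposite directions. Genes called in either stage were then compared between species over genes with the same symbol. With 12 mouse libraries, 4 genes were higher in both species (18 human and 59 mouse genes called higher of 10629, 0.0999 expected, Fisher's exact p = 2.47e-06). These were HIF3A (log2 7.30 in human and 4.28 in mouse), HSPA12B (7.31 and 3.96), ASIC4 (4.63 and 4.56) and FNBP1L (2.78 and 4.31), where the human call of HIF3A was lost without either WT day 5 library, and none was lower in both (10 and 29 called, 0.0273 expected, Fisher's exact p = 1). With 10 mouse libraries, 7 of 17 human genes were higher in both against 2.95 expected (Fisher's exact p = 0.0180), adding EPX (at least 130-fold in human, where WT day 5 had no counts and the call was lost without WT replicate 1, and log2 2.35 in mouse), DENND5A (5.15 and 3.19) and CBX6 (1.63 and 1.15), while 2 genes changed in opposite directions. The fetal globin genes HBG1 and HBG2 and the mouse embryonic genes have different symbols and are not part of this overlap.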

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

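Of the tests in this part, those by chemoreceptor share and by Hba-x, those of blood cell markers and those of the cell cycle genes were chosen only after the result was seen, as was the fit with 10 mouse libraries. The thinning of libraries and the splits of the libraries were chosen before.

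The results below were picked out because the KO effect differed between the mouse stages EB-S and EB-L in a direct test with 10 libraries, for genes named by the rule. Values are the KO effect in EB-S minus that in EB-L, with the effects in EB-L and EB-S in brackets. With all 12 libraries edgeR called 0 such differences, with 98 at an unadjusted p under 0.05, and DESeq2 called 0, while a block by column number within each genotype, added after the data were seen, gave 19.

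Mitosis and histone genes were the largest set. The mitosis genes Ccnb1 at -2.08 (-0.23 and -2.31), Ndc80 at -2.08 (0.34 and -1.74), Tpx2 at -1.92 (-0.16 and -2.07), Cdk1 at -2.12 (-0.25 and -2.37) and Spc25 at -2.43 (0.25 and -2.18) had adjusted p from 0.000726 to 0.00208. The histone genes Hist1h2ag at -2.06 (-0.32 and -2.38), Hist1h1d at -2.10 (0.06 and -2.05), Hist1h2ab at -2.04 (-0.42 and -2.46) and Hist1h2ad at -1.82 (-0.39 and -2.20) had adjusted p from 0.00274 to 0.00406. Other falls in the difference were those of Arhgef39 at -2.36 (-0.31 and -2.67), Git1 at -2.38 (0.03 and -2.35), Sapcd2 at -2.68 (1.59 and -1.08), Cul7 at -2.42 (3.85 and 1.43) and Icam4 at -1.52 (-1.13 and -2.64).

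Differences in the other direction included markers of other blood cells, with Ngp at 6.64 (3.28 and 9.92, a fitted value that rests on 0 counts in WT EB-S), Cd74 at 3.94 (5.56 and 9.50) and Cd22 at 2.32 (1.71 and 4.02). Erythroid and iron genes were Aco1 at 2.75 (-0.18 and 2.57), Pklr at 2.20 (1.83 and 4.03) and Xk at 1.18 (0.18 and 1.36), and the transcription factor genes Nfia and Nfix were at 1.75 (-0.66 and 1.09) and 1.13 (-0.26 and 0.87). The p53 targets Ccng1 at 2.25 (0.09 and 2.34) and Sesn2 at 1.90 (1.62 and 3.52), the replication genes E2f2 at 1.29 (-0.67 and 0.62) and Mcm6 at 1.29 (-0.40 and 0.89), Bcl2l13 at 1.11 (-0.11 and 1.00), Nedd9 at 3.65 (0.68 and 4.33), Evi2b at 3.56 (3.35 and 6.91) and Arsb at 3.59 (-3.70 and -0.11) complete the set. Over all of these genes the adjusted p ran from 0.000478 to 0.0483, and 14 of the 30 calls were kept when any 1 library was left out, where the count of calls ranged from 108 without KO EB-S number 3 to 647 without the WT EB-S library whose column is numbered 3.

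The lower mitosis and histone counts in KO EB-S form the first pattern weighed. Scaling between libraries moves every gene alike and is argued against, since the median log2 difference of the mitosis list minus that of all other tested genes was -1.55 (SD of 0.55 among its 30 members and 1.35 among the 13468 others) and that of the histone list -1.91 (0.64 among 59 and 1.34 among 13439). The other scalings hardly moved this comparison and do not test it. A lower share of erythroid cells as the only cause is argued against by the red cell membrane and late erythroid genes. Their median lay 1.51 above that of the mitosis genes, a difference that scaling cannot change, against an SD of 1.10 among 32 members. The SDs given here are spreads among genes, not among libraries, and the medians were known when both comparisons were chosen. A shift of KO EB-S cells along maturation stays open, since correlations of the KO difference with the WT stage difference, taken without a shared library, were 0.16, 0.26 and -0.10 over 6313 genes. The sort gated on CD44, and Cd44 itself was called lower in KO EB-L with 10 libraries. Without KO EB-L number 2 that call was lost, with a log2 difference of -1.32. Whether fractions of the same name hold the same stage in KO and WT was not tested. In WT maturation the mitosis and DNA replication lists were also lower, with medians of -0.50 and -0.435, against -1.59 and -0.81 in KO EB-S. The histone list had a median of -0.15 and the ribosomal list -0.88 in WT maturation, against -1.94 and -0.21 in KO EB-S. Red cell membrane genes had a median of 0.53 in WT maturation and -0.07 in KO EB-S, and glycolysis genes 0.16 and 1.09. Of single genes, Ldha and Bcl11a were called lower in WT maturation and higher in KO EB-S. An effect of the LRF loss on cell division is a biological candidate explanation that was not tested here.

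The second pattern is the higher level of markers of other blood cells in KO EB-S. Of 6 abundant transcripts written down for each cell type after the rise was seen, 5 were called higher for granulocytes or their RNA, 6 for B cells or their RNA and 5 for macrophages or their RNA, where the call of C1qb was lost without KO EB-S number 3 (adjusted p = 0.0626). Levels in KO and WT EB-S were 16.7 and 0.175 CPM for S100a8, 14.5 and 0.0303 for S100a9, 10.1 and 0.177 for Lyz2, 8.04 and 0 for Ngp, 73.5 and 0.0897 for Cd74, 7.36 and 0.25 for Cd79a, 10.2 and 0.836 for Vcam1 and 20.3 and 1.24 for Hmox1, a gene that is also in the heme and iron list, while Camp was at 0.661 and 0.266 and C1qc was not called (adjusted p = 0.0934). All but H2-Aa, H2-Ab1, H2-Eb1 and Hmox1 are members of the marker lists, so these counts restate the rise and do not test where it comes from. The sort for Ter119+CD71+ cells with CD44 and FSC gates selects against such cells, and other cells or their RNA and expression of these genes in KO erythroblasts themselves both stay open. The lymphocyte receptor gene Tnfrsf13c, also a B cell gene, went the other way and was called lower in KO EB-S. That call was lost without WT column 4 (log2 -4.17, adjusted p = 0.0522) and without either KO library.

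The third pattern is the place apart of the KO libraries numbered 1. Low depth alone is argued against, since the 10 other libraries thinned to 972714 counts detected at most 12813 genes, against 22595 and 22640. Wild-type material under a KO label is argued against by Hba-x, whose ratio to Beta-s was at least 766 times the highest WT ratio in these libraries. This sets them with the other KO-labelled libraries and does not check the KO label itself. In these libraries the olfactory and vomeronasal share was at least 52.4 times that of any other library. That share is part of the pattern itself, so it restates the spread of counts over genes that erythroblasts do not express. The source of these counts was not tested. No biological explanation was tested for this pattern.

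For the splits of the mouse libraries, 3 against 3 make 10 splits, too few for a share under 0.05. The real split called 72 genes in EB-L and 95 in EB-S with all 12 libraries, the highest other split 0 in each, so that 1 of the 10 splits gave as many. Between the WT stages the real split called 2530 genes with 10 libraries against 0 in the highest other (1 of 10). With all 12 libraries the real count was 0 between the WT stages and for the difference between KO effects. Any split gives at least 0 calls, so the counts of 10 of 10 and 30 of 30 splits that gave as many were fixed beforehand and test nothing.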

How the results depend on the processing

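The fit without the mouse KO libraries numbered 1, every value called 10 libraries and the block within a mouse genotype were chosen after the result was seen, the other settings before. No called value of a named gene, a list or a share reversed its direction, but calls were lost and counts of calls moved, and the cause was not tested except where stated. In 14 of 99 comparisons with another setting the excess of higher or lower calls turned. Between human WT stages it went from 0 higher and 4 lower to 179 and 110 without a filter and 3 and 2 without WT day 5 replicate 1. It went from 10 and 6 to 4 and 5 at day 0 without WT replicate 2 and from 21 and 9 to 138 and 153 at day 5 without KO replicate 1. With 10 mouse libraries, EB-L went from 891 and 860 to 996 and 1008 with DESeq2, 1368 and 1440 with 2 groups and 674 and 700 without WT column 4. EB-S went from 1891 and 1692 to 1837 and 1876, 1241 and 1558, and 1567 and 1931 in the same settings. Between WT mouse stages it went from 1037 and 1493 to 1405 and 1288 with DESeq2, and the difference in KO effects from 165 and 232 to 457 and 416 with the block, 259 and 228 without WT EB-S column 1 and 62 and 46 without KO EB-S number 3. Without a filter on low counts it was 309 at human day 0, 359 at day 5, 289 between WT stages and 21 for the human difference in KO effects, and in mouse (12 libraries) 121 in EB-L and 6 between WT stages. With DESeq2 the same human counts were 247, 277, 65 and 1, and the mouse ones 402 in EB-L, 622 in EB-S and 45 between WT stages, with 655 for the difference in KO effects with 10 libraries. With only the 2 groups compared they were 143 at day 0, 0 at day 5 (edgeR, where the unadjusted count was 926 in the fit of all groups and DESeq2 called 277), 31 in EB-L, 1916 between WT mouse stages and 2808 in EB-L with 10 libraries. With DESeq2 size factors 202 genes were called in EB-S. Without both KO libraries numbered 1 the mouse counts were 1751 in EB-L, 3583 in EB-S, 2530 between stages and 397 for the difference in KO effects.

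With the replicate block, 59 genes were called at human day 0 and 70 at day 5. The share differences of 4.35 and 9.97 points had exact p = 0.5 in the block, the smallest that 2 pairs allow. Values of replicates with the same number correlated at 0.13, 0.59, 0.18, -0.05, 0.25 and 0.12 between pairs of human groups over 9242 genes. No paired analysis was made between mouse KO and WT. The titles number both genotypes from 1 to 3, but the WT columns are numbered 1, 3 and 4. No label says that a number pairs KO with WT. The column numbers can pair EB-L with EB-S within a genotype, though no label says that they mark an animal. Values with the same number correlated over 6313 genes at 0.44, 0.11 and 0.34 in WT (10 libraries), where 1 of the 3 correlated as well with another number (0.12), and at 0.12 in KO. The replicate block within a genotype called 1955 genes between WT stages and 19 for the difference in KO effects with 12 libraries, and 2996 and 873 with 10. Of 94 called named values (10 libraries) 93 kept their call in it, Vcam1 between WT stages being at adjusted p = 0.0589, as did all 16 list calls.

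Genes shared between species were 34 with DESeq2 (32 higher against 5.65 expected, 2 lower against 2.36) beside 12 in opposite directions, and 7 with 10 libraries beside 2. With 10 libraries they were 61 with DESeq2 (44 higher against 26 expected, 17 lower against 19.6, Fisher's exact p = 0.782) beside 24 in opposite directions. With the replicate block they were 19 (16 higher against 6.76 expected, 3 lower against 3.96) beside 5. Genes shared between human stages were 127 with DESeq2 and 32 with the replicate block, and between mouse stages 259 with DESeq2, 1324 with 10 libraries and, of those, 880 with an absolute log2 fold change of at least 1, a limit that can only remove genes.

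Leaving out 1 library gave counts of 3 to 15 at human day 0, 19 to 291 at day 5, 2 to 5 between WT stages and 0 to 7 for the difference in KO effects. In mouse (12 libraries) they were 40 to 264 in EB-L, 47 to 404 in EB-S, 0 to 5 between stages and 0 to 0 for the difference, and with 10 libraries 825 to 1391, 2341 to 3688, 1609 to 2978 and 108 to 647. A group left with 1 library was assumed to vary like the others. Share differences ranged from 2.56 to 6.15 points at day 0, 9.08 to 10.9 at day 5, 3.34 to 3.67 in EB-L and 4.50 to 4.89 in EB-S.

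Of 33 called human values of named genes, 33 kept their call with either other scaling, without the filter, with DESeq2 and with the block, 17 with 2 groups and 11 without any 1 library. Of 259 mouse values (10 libraries), 187 kept theirs without any 1 library and 257 with DESeq2 size factors. Of 17 human list calls, 17 held with both scalings and the block and 0 with an estimated correlation, and of 36 mouse list calls (10 libraries) 3 did. Depth limits most the KO libraries numbered 1, with totals of 972714 and 1035361.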

Other observations

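The genes of this part were chosen only after their values were seen, and no further test was run on them. Mouse Zbtb7b, the gene of a related zinc finger factor, stood at 3.08, 2.60 and 2.78 CPM in WT EB-L and at 96.4 and 94.8 in KO EB-L numbers 2 and 3. In EB-S it stood at 1.54, 1.00 and 0.787 CPM in WT and at 68.3 and 82.8 in KO. Human ZBTB7B, which lay between 17.5 and 29.7 CPM in the 8 human libraries, was not called in either KO comparison.

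Human macrophage-list genes that passed when adjusted over the list alone were AXL and MERTK at day 0 and AXL, MERTK and CD68 at day 5, with AXL at log2 1.60 and 1.92. AXL encodes a receptor tyrosine kinase, and Axl was also called higher in mouse KO EB-L (2.58) and EB-S (2.20) with 10 libraries. In the Notch list, HES1 (2.33) and NOTCH3 (4.67) passed at day 5 when adjusted over the list alone, and in mouse the ligand gene Dll4 was called higher at both stages (7.84 and 7.08). The list as a whole had a median of -0.21 at day 5, 0.16 in EB-L and -0.07 in EB-S (10 libraries), and in mouse its members were called in both directions.

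Human WT day 5 replicate 1 detected 18070 genes against 13642 to 15871 in the other 7 human libraries.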
